A study of Homo sapiens and synthetic construct with 26 samples.

How the data were processed

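The series measured a transMPRA, a massively parallel reporter assay in which every construct carries both a candidate regulatory element that drives a barcoded reporter transcript and a gRNA that names a transcription factor gene or a control. Per the labels, the library was delivered with piggyBac transposase by electroporation into K562 cells, an established human erythroleukaemia line. Cells were harvested at day 5 and day 10 after transfection, from 2 library concentrations named lowMOI and highMOI, with 3 replicates each. Genomic DNA and poly(A) RNA were taken from each pool of cells, which gives 24 libraries in 8 groups of 3. A further 2 association libraries link barcodes to gRNAs. The groups were taken from the sample titles, because the GEO tags for condition and time hold each other's values.

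The count table deposited by the authors holds raw counts per barcode, gRNA, element and library, with no normalization, and lists only combinations with at least 1 count. Per the labels' protocols, RNA was reverse transcribed, and 3 PCR cycles added an index and a UMI of 10 bp to RNA and DNA amplicons before further amplification and 150 bp paired-end sequencing. Whether the deposited counts are collapsed UMIs or reads is not stated in the labels, and the file gives a single count, so a comparison of UMIs with reads was not run. The association file deposited by the authors has the unit other: it is a list of barcode sequences of 18 nt, each with a gRNA name and no measured value. The submitters' processing notes name Bowtie, with no version, and Bowtie2 2.2.5 and 2.3.5, with no role. The mode of perturbation (cutting, repression or activation), the expression of the targeted genes and the genome build of the coordinates in the element names are not given in the sources used here. Coordinates are therefore printed as the element names give them, and elements were not assigned to genes.

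Counts were summed over barcodes for each of the 2626 constructs, and per library. Totals ran from 978773 to 4501505 counts per library. A median construct held 11717 counts over the 24 libraries. The association list held 1763835 barcodes, of which 569496 (32.3%) had counts. Of the counted barcodes 0 were linked to more than 1 gRNA. The association list is named as one of unique associations, so this 0 may be built in. But 56.9% of the counted barcodes were counted with more than 1 element, with a mean of 2.40 elements per barcode. A barcode was therefore read together with the element that the count table gives in each line, and barcodes seen with 1 element only were taken as an alternative. Chi-square over degrees of freedom between libraries of 1 group was 1.14 to 11.75 over 24 pairs. This compares them with counting error only, and PCR duplicates would raise it if the counts are reads, so it does not show that the libraries are separate samples. None was treated as a duplicate.

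The pair effect is the log2 ratio of RNA to DNA of a construct relative to the typical gRNA on the same element. It was fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), in 1 model per element over the 24 libraries with 8 groups and no replicate block, with library sizes and TMM factors computed over that element's constructs. Constructs needed a mean of at least 10 counts over the DNA libraries and at least 10 counts in at least 3 libraries, which left 2622 of 2626. Benjamini-Hochberg adjustment ran over all constructs for each contrast, with a threshold of 0.05. The contrasts were RNA minus DNA in each condition and in the mean of the 4 conditions, day 10 minus day 5, and highMOI minus lowMOI. The guide-wide effect used counts summed per gRNA over elements with TMM over the 26 gRNAs. Element activity used counts summed per element over gRNAs with library totals as the only scaling, so that it is RNA over DNA relative to the whole library. The change in abundance used DNA counts summed per gRNA in the 12 DNA libraries. A second form of the pair effect, called the element-specific part, used offsets that remove the part of a gRNA's effect that its elements share; it was chosen after seeing the data.

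Further tests were a permutation of gene labels over gRNAs with 100000 permutations, Fisher's exact test, exact sign-flip tests over the 12 pools, and permutation tests with 100000 resamples, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A pool value is the log2 ratio of the RNA library to the DNA library that carries the same day, concentration and replicate number. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, where a list had at least 5 gRNAs. Figures were drawn with matplotlib 3.10.9.

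Results of the gRNAs of 1 targeted gene are not reported here, nor is a list test that needs them; these gRNAs stay in the fits and in counts over all gRNAs or constructs. The named items followed a rule set before the data were examined. For pairs, these were the 12 lowest and the 12 highest log2 effects among constructs past the threshold with the same sign in 4 conditions, and the 5 lowest and 5 highest in each day or concentration contrast. For gRNAs, they were the 12 lowest and 12 highest past the threshold, and for elements the 12 highest and 12 lowest. Alternatives were DESeq2 1.42.0 with its size factors, library totals or TMM, control gRNAs as the reference, other filters on low counts, distinct barcodes in place of counts, removal of barcodes above the 99th percentile, a replicate block, fits on the 6 libraries of a condition, and each library left out in turn. The odd-numbered and even-numbered barcodes, barcodes seen with 1 element, the mean of the 2 day 10 conditions and the control reference for the guide-wide effect and abundance were chosen after seeing the data.

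The fits were tested on simulated counts. With 200 of 2622 constructs changed, the fit of the mean of 4 conditions recovered 100% of constructs at a log2 change of -1 or 1, 88% at -0.5 and 90% at 0.5, and called 0.70% of unchanged constructs, which made up 8.25% of its calls, above the nominal 5%. This share was 3.27% to 8.79% in single conditions, highest at day 5 highMOI. In these fits of single conditions it recovered 52% to 68% at a log2 change of -0.5 or 0.5, and 88% to 100% at -1 or 1. The guide-wide fit recovered all of the changed gRNAs at log2 changes of 0.1, 0.2 and 0.5 in either direction, but also called 25% of unchanged gRNAs, with estimates between -0.024 and 0.024. The element-specific fit called 0% of constructs when only gRNAs changed on all elements, but 9.04% of unchanged constructs when 200 single constructs changed. In the element activity fit of day 10 minus day 5, 100% of elements at a log2 change of -0.5 or 0.5 were recovered and 1.10% of unchanged elements were called. The abundance fit recovered all gRNAs at changes of 0.1 and 0.3 in either direction and called 0% of the unchanged ones.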

Results

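The data describe how 26 gRNAs, each built into the same plasmid as a reporter, go with the transcript output of 101 reporter elements in K562 cells, an erythroleukaemia line. The elements are 200 bp long and their names class them as 75 positive regulators, 20 negative regulators, 3 scrambled positive regulators and 3 scrambled negative regulators. The gRNAs name 8 transcription factor genes, with 2 gRNAs for NRF1 and 3 for each of the others, and 3 are controls. The 101 elements and the 23 gRNAs that name a gene make 2323 constructs, the number the series' design text gives, and the controls bring the total to 2626. Of these, 2586 were counted in every one of the 24 libraries. The 3 libraries per group held 1727331 to 2256910 counts in day 5 lowMOI DNA, 1729945 to 2197485 in day 5 highMOI DNA, 1340145 to 2267255 in day 10 lowMOI DNA and 1392690 to 1803572 in day 10 highMOI DNA. RNA totals ran from 1521311 to 1761834 in day 5 lowMOI, from 3100606 to 4501505 in day 5 highMOI, from 978773 to 1325689 in day 10 lowMOI and from 2298984 to 2583060 in day 10 highMOI. All pools share a single set of plasmids and barcodes and nothing in the labels says that replicates came from separate transfections, so p-values measure only the spread between these pools.

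The first comparison asked whether a gRNA goes with the RNA of the reporters it is linked to, summed over elements. RNA over DNA was lowest for MYC_13, a gRNA for the proto-oncogene MYC that drives growth and proliferation, at a log2 of -0.72 ± 0.014 (SE of the edgeR fit) relative to the typical gRNA. GATA1_11, which names the erythroid regulator GATA1, lay at -0.55 ± 0.018, and NRF1_17, which names the activator nuclear respiratory factor 1, at -0.32 ± 0.0072. The ETS factor gRNA GABPA_8 followed at -0.22 ± 0.0053 and FOSL1_5, for an AP-1 subunit, at -0.18 ± 0.0050. The highest gRNAs were control_26 at 0.16 ± 0.0069, MYC_14 at 0.15 ± 0.0059, ATF4_1, for the stress-response factor ATF4, at 0.13 ± 0.0055 and control_25 at 0.11 ± 0.0044. MYC_13 was below 0 in 12 of 12 pools, as was GATA1_11, while MYC_14 was above 0 in 12 of 12. Over the 12 pools the SD was 0.24 for MYC_13, 0.47 for GATA1_11 and 0.044 for MYC_14. The SE of the fit therefore does not measure how far pools of different conditions lie apart.

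In edgeR's quasi-likelihood test 24 of 26 gRNAs passed the threshold, 12 lower and 12 higher, with an adjusted p of 1.34e-21 for MYC_13 and 6.79e-18 for GATA1_11. Further lower gRNAs were SP1_19, for a zinc finger protein that binds GC boxes, at -0.11, NRF1_16 at -0.098, FOSL1_4 at -0.065, SP1_20 at -0.052, GATA1_10 at -0.038 and GABPA_7 at -0.012. Against the typical gRNA the value of FOSL1_4 rests on day 5 highMOI (-0.28), since it lay at -0.015, 0.027 and 0.0081 in day 5 lowMOI, day 10 lowMOI and day 10 highMOI and above 0 in 5 of 12 pools. Further higher ones were GATA1_12 at 0.081, ATF4_2 at 0.075, MYC_15 at 0.070, control_24 at 0.049, GABPA_9 at 0.041 and FOSL1_6 at 0.029. Simulated unchanged gRNAs were called with values of up to 0.024, so the call of GABPA_7 lies within what the test gives with no change, and it ended, at -0.012 to -0.011, without DNA of day 10 highMOI replicate 1, DNA of day 5 lowMOI replicates 2 or 3, RNA of day 10 lowMOI replicate 1 or RNA of day 5 highMOI replicate 1. With the 3 control gRNAs as the reference, chosen after seeing the data, the median moved by -0.10 and 26 gRNAs passed, 22 lower and 4 higher. The controls themselves passed, at -0.054 for control_24, 0.0075 for control_25 and 0.058 for control_26, so a call alone does not separate a targeted gRNA from a control. Of the gRNAs reported, ATF4_1, ATF4_2, GATA1_12, MYC_14 and MYC_15 lay within that range. Under that reference FOSL1_6, GABPA_9, MYC_15, ATF4_2 and GATA1_12 changed sign, so their direction holds only against the typical gRNA. So did control_24, but as the lowest of the 3 controls that form the reference it falls below 0 by construction. FOSL1_4 was then lower in all 4 conditions, at -0.078 and -0.37 at day 5 and -0.10 and -0.12 at day 10 (lowMOI, then highMOI), each past the threshold. With library totals as the scaling 10 gRNAs were lower and 15 higher, and GABPA_7 changed sign to 0.018, while the call of GATA1_10 ended at -0.0078. With distinct barcodes counted GATA1_10 changed sign to 0.0063 and the call of FOSL1_4 ended at -0.013. Pair effects were also fitted with library totals within each element in place of TMM, and their median was taken over elements. These medians were -0.060 for NRF1_16, -0.019 for FOSL1_4, -0.0072 for SP1_20, -0.011 for GATA1_10, 0.021 for GABPA_7, 0.10 for GABPA_9 and 0.055 for FOSL1_6. Each was over 1.5 times away from the value above or of the other sign. With TMM the median of NRF1_16 was -0.068, which is less far away.

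**Figure D1:**
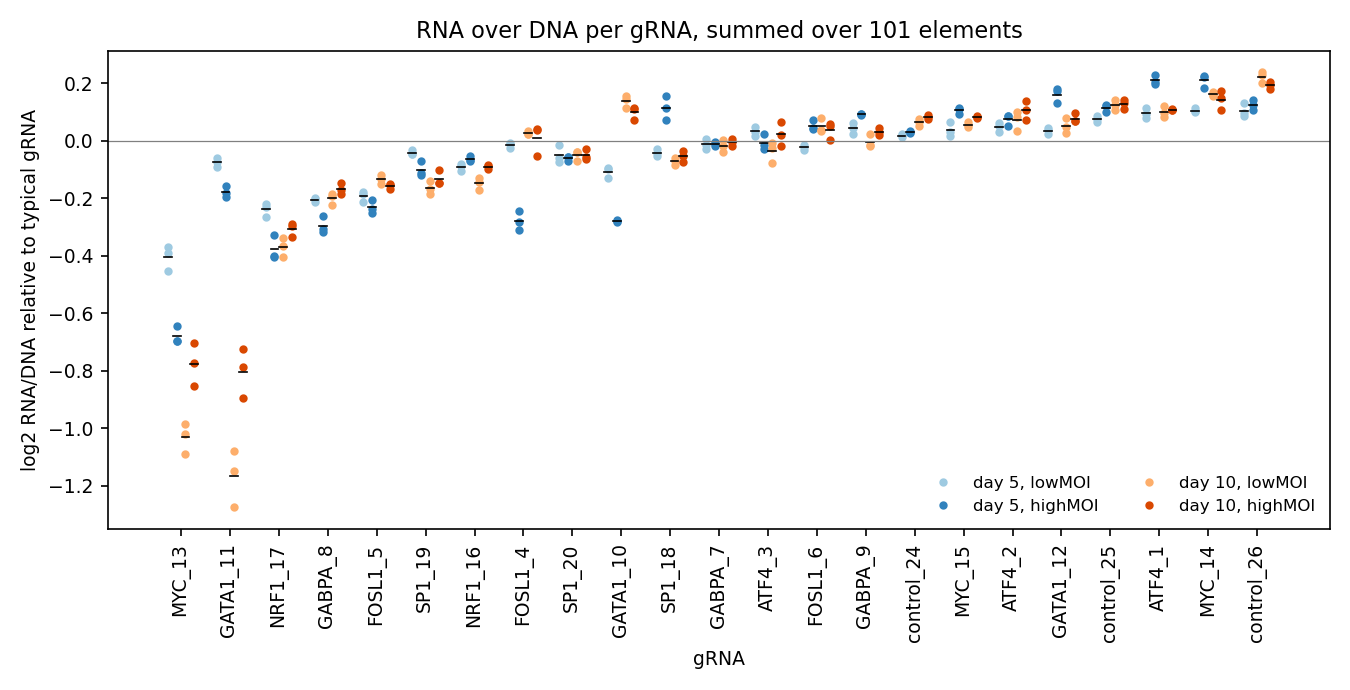
Log2 RNA over DNA relative to the typical gRNA (y axis) for 23 gRNAs (x axis, ordered by the mean), with a point for each of 12 pools coloured by day and concentration and a short line at the mean of the 3 pools of a condition. MYC_13 lies below 0 in all 12 pools and GATA1_11 falls mainly at day 10, while the small positive values of FOSL1_6, GABPA_9, MYC_15, ATF4_2, GATA1_12 and control_24 turn negative when the 3 control gRNAs are the reference.

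The gRNAs of a gene differed from each other. For MYC, MYC_13 was at -0.72 and MYC_14 and MYC_15 were at 0.15 and 0.070. For GATA1, the values were -0.038 for GATA1_10, -0.55 for GATA1_11 and 0.081 for GATA1_12. Both NRF1 gRNAs were lower, at -0.32 and -0.098. Across 100 elements the pair effects of gRNAs of the same gene had a mean Pearson r of -0.049 over 22 pairs of gRNAs, against 0.0094 for gRNAs of different genes, a mean that was not higher than with gene labels permuted 100000 times (one-sided permutation p = 0.946). These correlations are across constructs, which are not independent replicates. Of 741 called constructs with a gene's gRNA, 189 (25.5%) had a second gRNA of the same gene called in the same direction on the same element, against a median of 223 in 1000 permutations of the gene labels (one-sided permutation p = 0.691).

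Gene lists fixed before the data were examined held few of these genes. Among the erythroid and K562 regulators only GATA1 had gRNAs, of which 2 were lower and 1 higher. The bZIP list had ATF4 and FOSL1, with 2 of 6 gRNAs lower and 3 higher, and camera gave p = 0.681 with the preset and p = 0.678 with an estimated correlation. GABPA on the ETS list had 2 lower gRNAs and 1 higher, SP1 on the KLF/SP list had 2 lower and 0 higher, and MYC on the proliferation list had 1 lower and 2 higher. All 3 control gRNAs were higher. Counts adjusted over the list alone were the same for each of these lists.

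The next comparison asked which gRNA goes with a change on which element. In the mean of the 4 conditions 811 of 2622 constructs passed the threshold (edgeR, adjusted p under 0.05), 458 lower and 353 higher, and 641 of the 811 had the same sign in all 4 conditions. MYC_13 was lower on 96 of 100 elements tested, GATA1_11 on 88 of 101, NRF1_17 on 70, FOSL1_5 on 52 and GABPA_8 on 48, and these gRNAs had 0 constructs past the threshold in the other direction. MYC_14 was higher on 57 elements, GATA1_12 on 38, ATF4_1 on 37 and control_26 on 34. With control gRNAs as the reference 743 constructs passed, 685 lower and 58 higher, so the number of higher constructs holds only against the typical gRNA. Counting distinct barcodes in place of summed counts gave 444 constructs, 335 lower and 109 higher, and barcodes seen with 1 element only, chosen after seeing the data, gave 275.

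**Figure D2:**
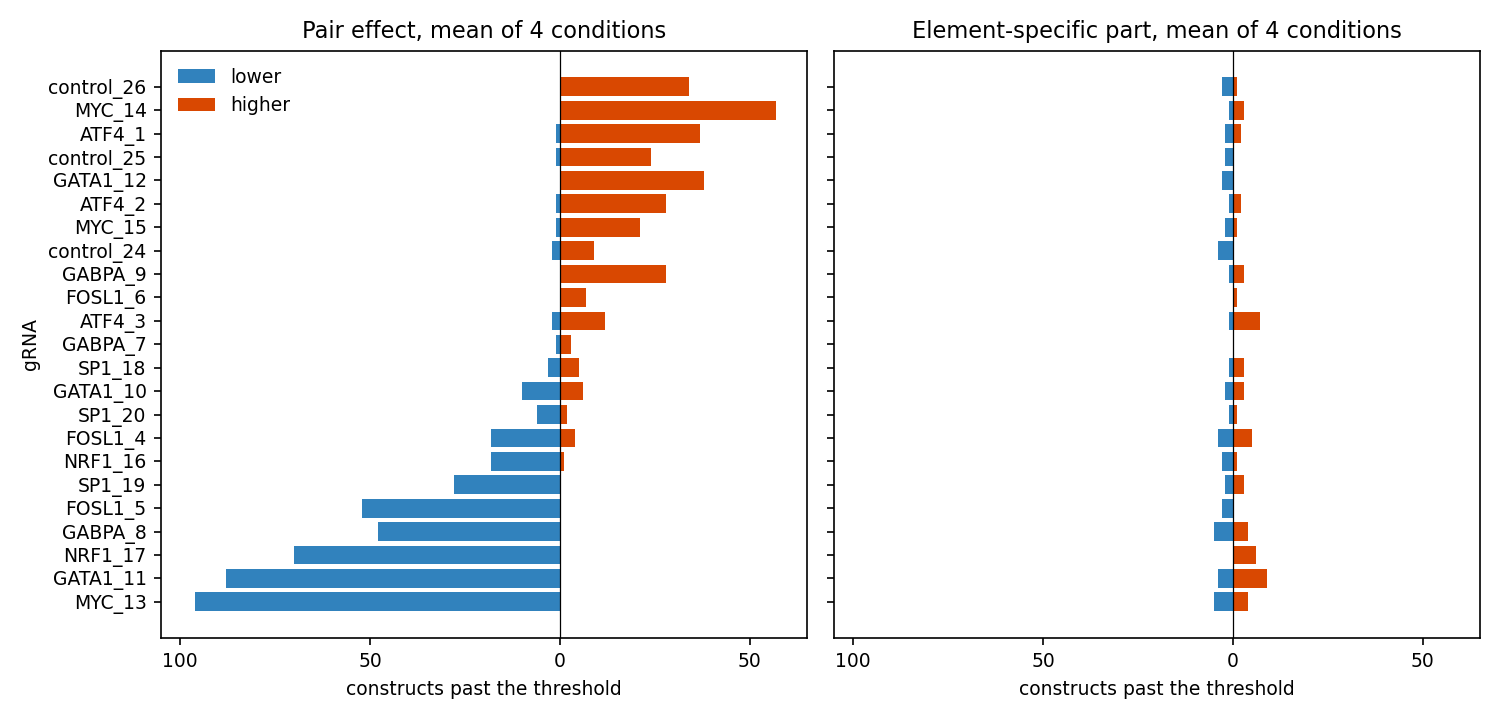
Number of constructs past the threshold in the mean of 4 conditions (x axis, lower to the left, higher to the right) for each of 23 gRNAs (y axis), for the pair effect and for the part of it that a gRNA's elements do not share. MYC_13 is lower on 96 elements in the pair effect and on 5 in the element-specific part, and over all 26 gRNAs the higher constructs fall from 353 to 58 when control gRNAs are the reference.

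Of the 12 lowest constructs with a stable sign, 11 carried MYC_13 and 1 carried GABPA_8. MYC_13 on element 76, a negative regulator (chromosome 15, 63141541 to 63141741), had a log2 effect of -1.77 ± 0.29 (SE, edgeR adjusted p = 3.74e-06), while MYC_14 on the same element was at 0.65 and MYC_15 at 0.096. MYC_13 on element 69, a positive regulator (chromosome 17, 79779746 to 79779946), lay at -1.06 ± 0.080 and on element 21 (chromosome 7, 106415221 to 106415421) at -0.93 ± 0.046, in 12 of 12 pools below 0 on both. On element 64, a positive regulator (chromosome 10, 126336466 to 126336666), MYC_13 was fitted at -2.98 ± 0.69 and GABPA_8 at -1.45 ± 0.34, but their RNA libraries held medians of 2 and 7 counts, with 0 in the lowest, so these sizes depend on the fit and are no bounds. MYC_13 was fitted at -1.15 on element 90, -1.06 on 68, -1.01 on 72 and 58, -0.99 on 87, -0.97 on 75 and -0.91 on 93. Its RNA libraries held medians of 18, 9, 17.5 and 18 counts on elements 76, 90, 58 and 87, with 0, 1, 0 and 2 in the lowest, so these sizes are uncertain too. On element 76 the mean is drawn down by day 10 lowMOI (-3.15), with -1.58 to -1.16 in the other conditions, and on element 90 by day 10 highMOI (-2.68), with -0.18 at day 10 lowMOI. Day 10 lowMOI was also the lowest condition on elements 58 (-2.36), 87 (-2.18), 72 (-2.02) and 68 (-1.93), where the others lay at -0.92 or above. The call on element 58 ended with control gRNAs as the reference (-0.51) and that on element 87 with distinct barcodes (-0.39).

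The highest constructs reached smaller values. GABPA_9 on element 64 had a log2 effect of 0.75 ± 0.18 (edgeR adjusted p = 0.00201) and on element 55, a positive regulator (chromosome 17, 71287651 to 71287851), 0.66 ± 0.14, where GABPA_8 lay at -1.45 and -0.46. MYC_14 was at 0.65 on element 76 and at 0.60 on element 10, a positive regulator (chromosome 10, 74080581 to 74080781), where MYC_13 was at -0.69 and MYC_15 at -0.56. FOSL1_4 was at 0.61 on element 100, a scrambled negative regulator, above 0 in 12 of 12 pools. ATF4_3 was at 0.54 on element 10, with ATF4_2 at -0.31 there, and at 0.51 on element 58, and ATF4_1 was at 0.50 on element 91. Control gRNAs were among them, with control_25 at 0.49 on element 59 and control_26 at 0.49 on element 33. With control gRNAs as the reference the call of control_25 on element 59 ended (0.19), and with distinct barcodes so did those of control_26 on element 33 (0.19), ATF4_3 on element 10 (0.15) and GABPA_9 on element 55 (0.32). From barcodes seen with 1 element only, chosen after seeing the data, GABPA_9 on element 64 (-0.24 ± 0.48, SE), FOSL1_4 on element 100 (-0.33 ± 0.28) and ATF4_3 on element 10 (-0.15 ± 0.25) changed sign. None of these reversed values passed the threshold, so they fix no direction. ATF4_2 on element 49 (0.50) lost its call, at 0.39 to 0.48, without DNA of day 10 highMOI replicate 3, day 10 lowMOI replicate 1, day 5 highMOI replicate 3 or day 5 lowMOI replicate 3, or RNA of day 5 highMOI replicate 2 or day 5 lowMOI replicate 2. ATF4_1 on element 59 (0.51) lost its call, at 0.39 to 0.44, without RNA of day 10 highMOI replicate 1, day 10 lowMOI replicate 1 or day 5 highMOI replicate 2.

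Of the control constructs 70 of 301 (23.3%) were called, against 741 of 2321 (31.9%) of the others, an odds ratio of 0.65 (0.81 at a threshold of 0.1), and 67 of the 70 were higher. Fisher's exact test gave a two-sided p of 0.00225 (0.115 at 0.1), but it counts constructs as independent, while calls cluster by gRNA and the controls are only 3 gRNAs, so no difference is read from it. With control gRNAs as the reference 25 control constructs (8.31%) and 718 others (30.9%) passed. The control constructs form that reference, so part of their fall is built in. After the part shared by a gRNA's elements was removed, 115 constructs passed, 53 lower and 62 higher, including 10 with control gRNAs. In simulations with single constructs changed this fit also called 9.04% of the unchanged constructs, so the 115 cannot be read as a number of true changes.

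Within conditions, fewer constructs passed, and lower constructs outnumbered higher ones in each. There were 114 at day 5 lowMOI (80 lower, 34 higher), 301 at day 5 highMOI (222 lower, 79 higher), 456 at day 10 lowMOI (280 lower, 176 higher) and 316 at day 10 highMOI (221 lower, 95 higher). With control gRNAs as the reference these splits were 106 lower and 4 higher, 269 and 3, 426 and 93, and 334 and 12. GATA1 gRNAs had 8 lower constructs at day 5 lowMOI and 83 at day 10 lowMOI, and 32 and 75 at highMOI. Different gRNAs made up these counts. At day 5 GATA1_10 held 6 and 29 of them (lowMOI, then highMOI) and GATA1_11 only 2 and 3. At day 10 GATA1_11 held 81 and 75, while GATA1_10 had 0 lower constructs and 23 and 6 higher ones. The higher constructs of all GATA1 gRNAs numbered 5 and 16 at day 5 and 33 and 10 at day 10. MYC gRNAs had 29 lower constructs at day 5 lowMOI and 79 at day 10 lowMOI, but 72 and 64 at highMOI. Barcodes seen with 1 element only gave 1, 11, 155 and 45 constructs, and the element-specific part 8, 3, 102 and 4. Fits on the 6 libraries of a condition alone gave 175, 966, 170 and 242 constructs, and DESeq2 gave 195 at day 5 lowMOI. Day 5 lowMOI fell to 46, 43 and 44 without DNA replicate 1, 2 or 3, day 5 highMOI to 187 without DNA replicate 2 and to 189 and 194 without RNA replicates 2 and 3, and day 10 highMOI to 204 and 209 without DNA replicates 1 and 2.

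The harvest days were compared through the difference of RNA over DNA between day 10 and day 5. GATA1_11 changed most, from a guide-wide log2 of -0.075 at day 5 lowMOI and -0.18 at day 5 highMOI to -1.16 and -0.80 at day 10, a difference of -0.85 ± 0.036 (SE, edgeR adjusted p = 2.93e-15). MYC_13 had a difference of -0.36 ± 0.028, which was -0.63 at lowMOI (from -0.40 to -1.03) and only -0.097 at highMOI (from -0.68 to -0.78). GATA1_10 went the other way, from -0.11 and -0.28 at day 5 to 0.14 and 0.099 at day 10, a difference of 0.31 ± 0.010. At day 10 it lay at 0.0054 (not called) and -0.032 (called lower) with control gRNAs as the reference, so the difference holds (0.26) but a value above 0 does not. FOSL1_4 had a difference of 0.16, made up of 0.29 at highMOI and 0.042 at lowMOI, where it did not pass. In all, 18 gRNAs differed between the days, 8 lower and 10 higher at day 10, and 20 with control gRNAs as the reference, 16 lower and 4 higher.

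Among single constructs, 167 differed between the days, 97 lower and 70 higher at day 10. GATA1_11 accounted for 68 of the lower ones and MYC_13 for 18, and GATA1_10 for 44 and FOSL1_4 for 15 of the higher ones. The lowest were GATA1_11 on element 87 at -1.38 ± 0.28, on element 76 at -1.35 (with 0 counts in the lowest RNA library), on element 20 at -1.19 and on element 78 at -1.17, and MYC_13 on element 66 at -1.22. The highest was GATA1_10 on element 3, a positive regulator (chromosome 1, 228678186 to 228678386), at 1.14 ± 0.15 (edgeR adjusted p = 9.95e-07), followed by FOSL1_4 on the same element at 0.79 and GATA1_10 on element 16 at 0.78 and on element 9 at 0.70. GATA1_10 on element 16 (0.78) lost its call, at 0.64 to 0.76, without DNA of day 10 highMOI replicate 1, DNA of day 5 highMOI replicate 2, DNA of day 5 lowMOI replicate 2, RNA of day 10 highMOI replicate 3 or RNA of day 5 highMOI replicate 1. With distinct barcodes the calls of GATA1_11 on elements 87 (-0.88) and 76 (-0.77) and of MYC_13 on element 66 (-0.98) ended. DESeq2 gave 262 constructs, 123 lower and 139 higher, and control gRNAs as the reference gave 121, 95 lower and 26 higher, but barcodes seen with 1 element only gave 17 and the element-specific part gave 5.

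The library concentrations were compared in the same way. Averaged over the days, the guide-wide difference of highMOI minus lowMOI passed for 17 gRNAs, 6 lower and 11 higher, from -0.14 ± 0.019 for FOSL1_4 and -0.11 ± 0.010 for GATA1_10 to 0.13 ± 0.036 for GATA1_11. This average hides opposite differences at the 2 days: MYC_13 differed by -0.28 ± 0.039 at day 5 and 0.25 ± 0.041 at day 10 (edgeR adjusted p = 2.36e-06 and 5.71e-05) but by -0.011 on average, GATA1_11 by -0.10, which did not pass, and 0.36, and NRF1_17 by -0.14 and 0.062. At day 5 alone 17 gRNAs passed, 8 lower and 9 higher, and at day 10 alone 4, all higher. Under the control reference the difference passed for 12 gRNAs averaged over the days, 6 lower and 6 higher, for 17 at day 5, now with GATA1_11 (-0.13), and for only 2 at day 10, GATA1_11 and MYC_13, since the calls of NRF1_16 (0.059) and NRF1_17 (0.063) ended. Among constructs 17 passed, 12 lower and 5 higher. The largest difference was that of control_25 on element 101, a scrambled negative regulator, at 1.63 ± 0.41, but its lowest RNA library held 0 counts, and its call ended, at 1.20 to 1.72, without DNA of day 5 highMOI replicates 1, 2 or 3, day 5 lowMOI replicates 1 or 3 or day 10 highMOI replicates 2 or 3, or RNA of day 5 highMOI replicates 1 or 3, day 5 lowMOI replicates 1 or 3, day 10 highMOI replicate 1 or day 10 lowMOI replicate 3. With barcodes seen with 1 element only it lay at -0.49 ± 1.08 (SE, not called), too uncertain to give a direction. Of the other 9 constructs that the naming rule picked, 4 also lost their calls when single libraries were left out and are not given here. Of the 5 that did not, FOSL1_4 on element 44 differed by -0.29 ± 0.053 (edgeR adjusted p = 0.000131), GATA1_10 on elements 53 and 5 by -0.36 and -0.33, GATA1_12 on element 72 by 0.38 and GATA1_11 on element 19 by 0.27. The number rose to 56 with DESeq2, to 47 without RNA of day 10 lowMOI replicate 2 and to 30 without RNA of day 5 lowMOI replicate 2, and fell to 5, all lower, with control gRNAs as the reference to 7, all higher, with distinct barcodes, to 3 with barcodes seen with 1 element only and to 0 in the element-specific part. Of these 5 only FOSL1_4 on element 44 passed with control gRNAs as the reference, and with distinct barcodes its call ended (-0.047).

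Element activity asked which elements gave more or less RNA per DNA than the whole library. In the mean of the conditions element 49, a positive regulator (chromosome 9, 34992466 to 34992666), was highest at a log2 of 1.79 ± 0.069 (SE of the edgeR fit), followed by the positive regulators 24 (chromosome 18, 3652941 to 3653141) at 1.71, 21 at 1.58, 45 (chromosome 15, 51520761 to 51520961) at 1.57, 19 at 1.46 and 2 at 1.28. Element 49 was thinly covered, with only 22 of its constructs past the filter on low counts. At day 5 highMOI element 21 was highest instead. The lowest were the scrambled negative regulators 100 at -4.53 ± 0.054 and 101 at -4.09 ± 0.027, then the positive regulator 16 (chromosome 2, 232527101 to 232527301) at -3.82 and the negative regulator 91 at -3.66. All of these kept their sign in 12 of 12 pools. Positive regulators had a mean of -0.56 ± 1.46 (SD, n = 75) and negative regulators of -1.15 ± 1.21 (SD, n = 20), a difference of 0.59 that a two-sided permutation test did not separate from 0 (p = 0.101). In single conditions that difference was 0.55, 0.43, 0.75 and 0.63, with permutation p of 0.121, 0.202, 0.0516 and 0.0963.

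By edgeR 97 of 101 elements passed, 67 lower and 30 higher. TMM scaling moved the median by 0.53 and gave 52 lower and 46 higher, and DESeq2 moved it by 0.63 and gave 48 lower and 51 higher, so activity is reported relative to the library total and not to 0. Between the days 83 elements differed, 62 lower and 21 higher at day 10. TMM moved that median by 0.17 (45 lower, 38 higher) and DESeq2 by 0.35 (26 lower, 53 higher). Among the elements named above, element 16 had the most negative difference, and the most positive was 0.52 ± 0.14 for element 49. Between concentrations 55 elements differed, 13 lower and 42 higher at highMOI, against 21 and 23 with TMM and 25 and 18 with DESeq2, which moved the median by -0.12, and against 25 elements in all with barcodes seen with 1 element only.

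**Figure D3:**
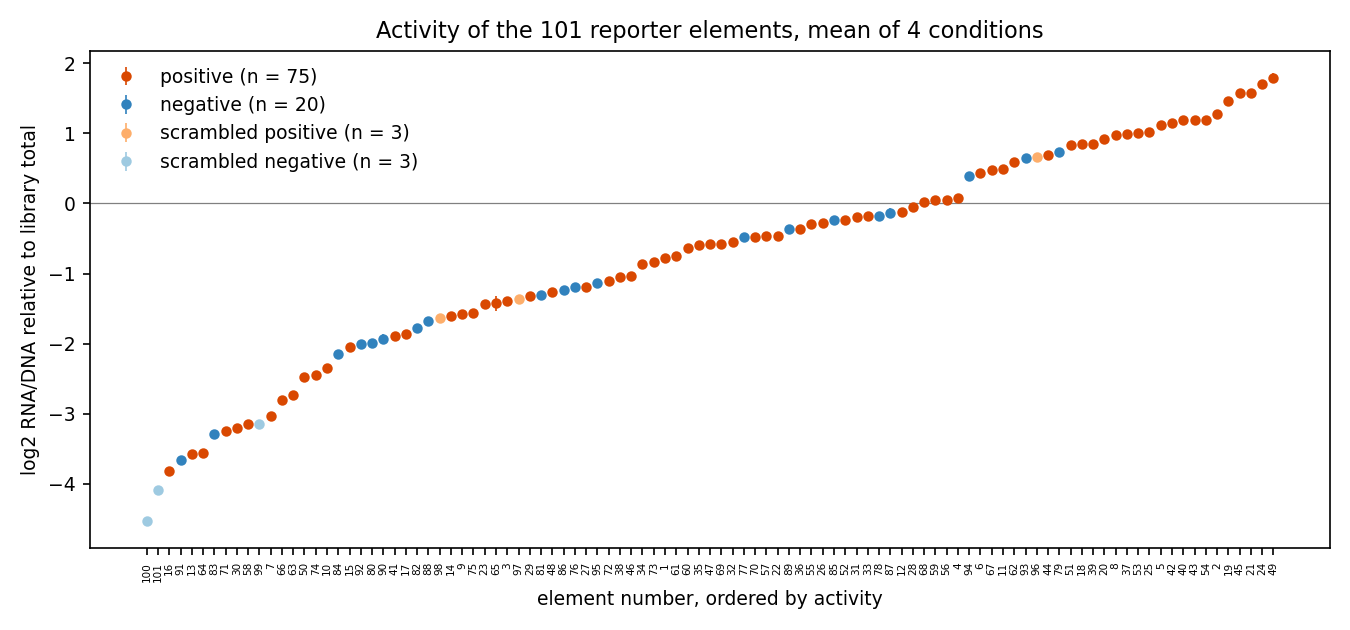
Log2 RNA over DNA relative to the library total (y axis), as the mean of 4 conditions with its standard error, for the 101 elements (x axis, ordered by activity), coloured by the class in the element name. Positive regulators span -3.82 to 1.79 and negative regulators -3.66 to 0.73, and the scrambled negative regulators lie at -3.14 or below.

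Each scrambled element shares its name's coordinates with an unscrambled one. All 3 negative regulators were more active than their scrambled counterparts, by 1.95 ± 0.35 (SD over 12 pools) for element 76 over 99, by 4.06 ± 0.34 for 77 over 100 and by 3.91 ± 0.15 for 78 over 101. Among positive regulators, element 2 exceeded 97 by 2.65 ± 0.25, element 3 exceeded 98 by 0.24 ± 0.33, above 0 in 9 of 12 pools (exact sign-flip test, p = 0.0327, which takes the pools as independent, so that no difference is read from it), and element 1 lay below 96, with a difference of -1.43 ± 0.29. The other 5 pairs gave an exact p of 0.000488 by the same test, the smallest that 12 pools allow. It too takes the pools as independent, so it is not read as the strength of these differences. Over the 6 pairs the mean difference was 1.90 ± 2.15 (SD), with an exact two-sided p of 0.0938. Pairs of elements that overlap in their coordinates also differed: element 15 was lower than 31, shifted by 30 bp, by a difference of -1.85 ± 0.17, element 58 lower than 74, shifted by 15 bp, with -0.71 ± 0.17, and element 38 lower than 60, shifted by 25 bp, with -0.42 ± 0.15, each below 0 in 12 of 12 pools.

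The last comparison followed each gRNA's share of the DNA between harvests, which asks whether cells that carry a gRNA became rarer or more frequent. MYC_13 fell by 0.31 ± 0.012 (log2, SE, edgeR adjusted p = 9.25e-12) and GATA1_11 by 0.25 ± 0.0094. NRF1_17 fell by 0.13, SP1_19 by 0.084, NRF1_16 by 0.056, SP1_20 by 0.038 and ATF4_3 by 0.032. FOSL1_4 rose by 0.14 ± 0.010 and GATA1_10 by 0.11. In all 18 of 26 gRNAs passed, 9 lower and 9 higher at day 10.

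The fall of MYC_13 was -0.34 at lowMOI and -0.28 at highMOI, and that of GATA1_11 was -0.33 and -0.18, a difference between concentrations of 0.15 ± 0.018 (edgeR adjusted p = 4.09e-05). The control gRNAs lay at 0.0078, 0.012 and 0.023. With them as the reference 13 gRNAs passed, 10 lower and 3 higher, while library totals gave 22, 8 lower and 14 higher, DESeq2 gave 16, 10 lower and 6 higher, and barcodes seen with 1 element only gave 11. The gRNAs control_24 and SP1_18, at 0.012 and 0.014, changed sign with control gRNAs as the reference, and the calls of GATA1_12, control_25 and ATF4_1 ended at 0.0056, 0.0086 and 0.013. GABPA_7 (-0.010) changed sign with distinct barcodes and GABPA_9 (-0.018) with barcodes seen with 1 element only. Camera did not call the bZIP list (p = 0.370, and 0.460 with an estimated correlation).

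**Figure D4:**
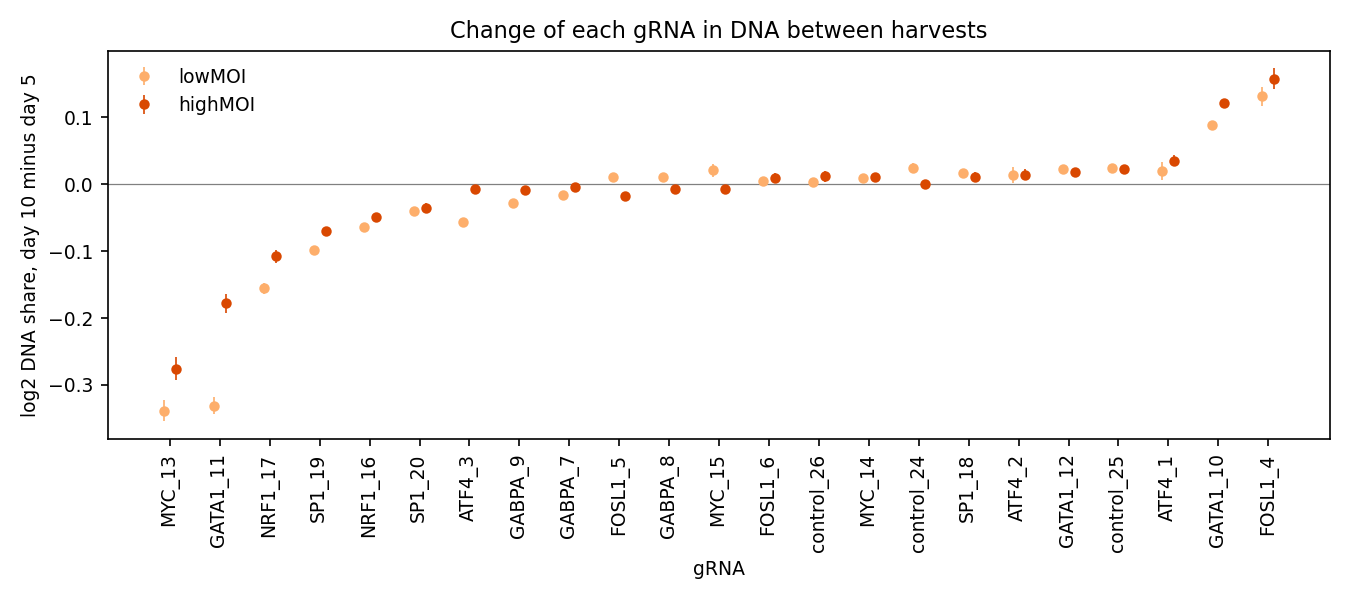
Log2 change of each gRNA's share of DNA from day 5 to day 10 (y axis) with its standard error, at lowMOI and highMOI, for 23 gRNAs (x axis, ordered by the mean of both). MYC_13 and GATA1_11 fell by 0.31 and 0.25, while FOSL1_4 rose by 0.14; control_24 and SP1_18, at 0.014 or less, change sign when control gRNAs are the reference.

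Replicates gave close values for constructs as such and looser ones for the part that compares gRNAs. Over 12 replicate pairs within conditions, log2 RNA over DNA with a pseudocount of 1 CPM had a mean Pearson r of 0.948 across constructs, from 0.899 to 0.985, and 0.922 between conditions. After centring on each element the mean r was 0.344 within conditions, from 0.126 to 0.635, and 0.261 between them. Constructs are not independent replicates, so no p-value is given.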

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

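The tests of a few barcodes, of loss of cells, of the element's own sequence, of shared barcodes, of targeted genes on single elements and of DNA that was not integrated were chosen only after the result was seen; those of sequencing depth, of a reference that includes active gRNAs and of other splits were not. Results appear here because an effect differed between days or between concentrations in a test of the difference itself. For pairs, 167 constructs differed between day 10 and day 5 and 17 between highMOI and lowMOI. For the guide-wide effect the numbers were 18 and 17 gRNAs, for element activity 83 and 55 elements, and for the change in DNA abundance 6 gRNAs differed between concentrations.

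Among the gRNAs reported, the guide-wide difference of day 10 minus day 5 was -0.85 for GATA1_11, -0.36 for MYC_13, -0.099 for SP1_18, -0.077 for SP1_19, -0.054 for GABPA_9, -0.049 for ATF4_1, -0.042 for NRF1_16 and -0.034 for GATA1_12. It was 0.030 for FOSL1_6 and control_25, 0.049 for control_24, 0.065 for FOSL1_5, 0.066 for GABPA_8, 0.092 for control_26, 0.16 for FOSL1_4 and 0.31 for GATA1_10. With control gRNAs as the reference FOSL1_6 (-0.027), control_25 (-0.026) and control_24 (-0.0074) changed sign, of which only control_25 passed, and the calls of FOSL1_5 (0.0088) and GABPA_8 (0.0090) ended. The difference of highMOI minus lowMOI was -0.14 for FOSL1_4, -0.11 for GATA1_10, -0.038 for NRF1_17, -0.031 for FOSL1_5 and -0.029 for GABPA_8. It was 0.022 for control_25, 0.031 for FOSL1_6, 0.041 for GABPA_9, 0.044 for NRF1_16 and MYC_14, 0.047 for MYC_15, 0.062 for ATF4_1, 0.076 for GATA1_12, 0.087 for SP1_18 and 0.13 for GATA1_11, averages over days that hide opposite differences such as -0.28 at day 5 and 0.25 at day 10 for MYC_13. With that reference the calls of control_25 (0.010), FOSL1_6 (0.020), GABPA_9 (0.030) and NRF1_16 (0.033) ended. The change in DNA abundance differed between highMOI and lowMOI by -0.030 for FOSL1_5, 0.029 for SP1_19, 0.033 for GATA1_10, 0.048 for NRF1_17, 0.049 for ATF4_3 and 0.15 for GATA1_11. With control gRNAs as the reference 8 gRNAs passed here, 0 lower and 8 higher. The call of FOSL1_5 (-0.022) then ended and MYC_13 (0.070) passed.

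The first pattern is that RNA over DNA of MYC_13, GATA1_11 and NRF1_17 is lower on most elements. A few barcodes do not carry it. Odd and even barcodes gave medians whose smallest ratio over the 3 gRNAs was 0.951, though a few barcodes could hardly move a median over elements. Summed per gRNA, where they could, odd and even barcodes gave -0.71 and -0.75 for MYC_13, -0.56 and -0.56 for GATA1_11 and -0.33 and -0.33 for NRF1_17. An effect that needs the element's own sequence cannot be told apart from one that does not: the smallest ratio of the median on the 6 scrambled elements to that on positive ones was 0.806, but 56.9% of barcodes were counted with more than 1 element, so that RNA of other elements may be counted on scrambled ones, and with barcodes seen with 1 element only the ratio was 1.29 with an SD over scrambled elements of 0.74 to 1.59. Loss or gain of cells that carry a gRNA, while part of the DNA gives no RNA, stays open: across 26 gRNAs the change in DNA share and the change in RNA over DNA from day 5 to day 10 had a Pearson r of 0.827 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 2.5e-05 over 5 relations) and a Spearman rho of 0.559 (p = 0.00336, adjusted 0.00525), and r was 0.702 without MYC_13 and GATA1_11. It was 0.897 at lowMOI (rho 0.689) and 0.644 at highMOI (rho 0.279, permutation p = 0.167), and 0.819 or 0.834 when the DNA share came from one parity of barcodes and the ratio from the other. Both changes had the same sign for 25 of 26 gRNAs at lowMOI but for 13 at highMOI. There NRF1_17 fell in DNA share (-0.11) while its ratio rose by 0.070, or by 0.025 (not called) with control gRNAs as the reference. These are changes between days, while the pattern is a level. MYC_13 already lay at -0.40 and -0.68 at day 5 (lowMOI, then highMOI) and NRF1_17 at -0.24 and -0.38. GATA1_11 lay at only -0.075 and -0.18 at day 5, with 2 and 3 elements called lower, against 81 and 75 at day 10. For GATA1_11 the pattern is thus mainly one of day 10. An effect of the named genes on reporter transcription in general also stays open, untested, because target expression and the mode of perturbation are not given.

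The second pattern is that constructs pass the threshold on single elements, with control gRNAs among them. A set of barcodes shared by all replicates may carry part of it. Element-specific effects had a mean r over 26 gRNAs of 0.134 between odd and even barcodes (0.209 for control gRNAs). In all, 5 constructs were called in both where 62 and 58 were called in each. Odd or even barcodes alone hold fewer counts, and noise also lowers r and the calls in both. The test therefore cannot separate shared barcodes from noise. A reference that includes active gRNAs is not settled, since 8.31% of control constructs still passed with control gRNAs as the reference, between the bounds of 5% and 10%. These constructs form that reference, so their effects centre on 0 by construction (14 lower and 11 higher, against 3 and 67 before). Part of the fall from 23.3% is therefore built in. An effect of the targeted genes on single elements cannot be told apart from none with 3 control gRNAs: 105 of 2321 such constructs against 10 of 301 passed (odds ratio 1.38, 95% interval 0.710 to 2.99, Fisher's exact test, p = 0.453, which counts constructs of a gRNA as independent). Among the 5, chosen after their values were seen, only GATA1_11 on element 5 was higher, with element-specific effects of 0.43 and 0.40 from odd and even barcodes. GATA1_11 was lower on element 19 (-0.14 and -0.13) and on element 25 (-0.20 and -0.21). FOSL1_4 was lower on element 9 (-0.37 and -0.19) and on element 19 (-0.16 and -0.11).

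The third pattern is that lowMOI lay closer to highMOI in combinations of barcode and element in day 5 DNA than in RNA or at day 10, though below it. The estimated number of combinations (Chao1) was 935884 ± 40189 (SD, n = 3) at lowMOI and 1013156 ± 15372 at highMOI, a ratio of 0.924, against 0.473 in RNA, and at day 10 the ratios were 0.501 in DNA and 0.592 in RNA. How far sequencing depth accounts for it is not settled, since the ways to allow for depth differ. With every library thinned to the same total the day 5 ratio was 0.278 higher in DNA than in RNA, against 0.456 before. The RNA ratio moved from 0.486 to 0.665. With Chao1, which also estimates unseen combinations, the difference stayed at 0.451 and the RNA ratio at 0.473. The common total, 978773 counts, lies near the estimated number of combinations in day 5 DNA, so depth limits the thinned DNA numbers. DNA of plasmid that was not integrated may contribute at day 5, where the DNA ratio exceeded the RNA ratio by 0.451. A biological difference between the concentrations was not tested.

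Other splits of the libraries gave as large a count in 1 of 100 (the real one) for the mean of 4 conditions (811 constructs, highest other 228), the day difference (167, 120), the guide-wide effect (24, 11), DNA abundance (18, 11), element activity (97, 75) and its day (83, 65) and concentration differences (55, 41). This ranks the real split first among random regroupings of these libraries, a share under 0.05, and no more. For the mean, the guide-wide effect and element activity the splits exchange RNA and DNA libraries. These can differ through their preparation alone, so the rank does not show that a gRNA or an element acts. The pools are also not known to be separate transfections. For the concentration difference of constructs 2 of 100 splits gave as many as the real 17, and the other gave 38, so a structure of the libraries other than concentration can give more. Within single conditions the 10 splits are too few for a share under 0.05; the real and highest other counts were 114 and 0 at day 5 lowMOI, 301 and 0 at day 5 highMOI, 456 and 7 at day 10 lowMOI and 316 and 0 at day 10 highMOI.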

How the results depend on the processing

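The odd-numbered and even-numbered barcodes, barcodes seen with 1 element, the element-specific part, the mean of the 2 day 10 conditions, and the control reference for the guide-wide effect and abundance were chosen after seeing the data; the other alternatives were set before the data were examined. Counts stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless fewer counts show it. DESeq2 gave 195 constructs at day 5 lowMOI, 262 for the day and 56 for the concentration difference, and control gRNAs as the reference gave 5 for the latter. Distinct barcodes gave 444 constructs in the mean of 4 conditions, 35, 109, 171 and 181 in the conditions (day 5 lowMOI and highMOI, day 10 lowMOI and highMOI), 7 for the concentration difference, and 94 elements. The 6 libraries of a condition alone gave 175, 966 and 170 in the first 3 conditions. The mean of the 2 day 10 conditions gave 396. At a threshold of 0.1 the odds ratio of control gRNAs was 0.81 and lost its call. Odd barcodes, with fewer counts, gave 19, 117 and 156 at day 5 lowMOI, day 5 highMOI and day 10 highMOI, and even barcodes gave 30, 103, 301 and 145 in the 4 conditions, 111 for the day and 11 for the concentration difference. Barcodes seen with 1 element gave 275, then 1, 11, 155 and 45 in the conditions, 17 and 3 for the differences, 11 gRNAs in abundance and 25 elements for concentration. The element-specific part left 115, then 8, 3, 102 and 4, and 5 and 0 for the differences; at an unadjusted p under 0.05, 215 constructs passed for concentration in edgeR, and no other tool was run on it.

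Leaving out a library gave 724 to 885 constructs in the mean of 4 conditions, 43 to 149 and 187 to 365 at day 5, 380 to 511 and 204 to 371 at day 10 (lowMOI, then highMOI), 135 to 219 for the day and 12 to 47 for the concentration difference, 23 to 25 gRNAs guide-wide, 16 to 19 in abundance, and 96 to 98, 80 to 86 and 52 to 61 elements in activity and its differences. Replicate numbers meet the bar for pairing (every same-numbered residual correlation over 0.1) only for RNA of day 5 with day 10 at highMOI, at 0.106 to 0.171, against 0.030 to 0.067 at lowMOI. RNA and DNA of the same number reached 0.057 to 0.072 at day 10 highMOI and 0.040 to 0.058 at day 10 lowMOI, above the other numbers (at most 0.010), but -0.028 to 0.033 at day 5. With a replicate block 777 constructs passed in the mean, 111, 281, 437 and 293 in the conditions, 152 and 17 for the differences, 24 gRNAs guide-wide, 18 in abundance, and 96, 81 and 54 elements. As a hint from the data, RNA barcodes overlapped DNA barcodes of their own number more than others at day 10 (1.63 against 1.42 times chance at lowMOI, 1.44 against 1.35 at highMOI) but not at day 5.

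Of the values for named items that are reported, 3159 kept their direction and call, 267 kept the direction only, 21 reversed and 4 moved in size. The 4 are guide-wide values taken as the median of pair effects fitted with library totals. They are those of GABPA_8 (-0.16), NRF1_16 (-0.060), SP1_20 (-0.0072) and GABPA_9 (0.10). By that median FOSL1_4 (-0.019), GATA1_10 (-0.011) and FOSL1_6 (0.055) changed by over 1.5 times, but by less than their SD over 12 pools. Leaving out 1 library ended a call of ATF4_2 on element 49 and ATF4_1 on element 59 in the mean, of GATA1_10 on element 16 between the days, of control_25 on element 101, FOSL1_4 on element 21, GATA1_11 on element 25, FOSL1_5 on element 35 and ATF4_1 on element 40 between concentrations, of GABPA_7 guide-wide, and of control_24 and SP1_18 in abundance. All 24 named elements kept theirs under every setting that could be computed for them. Reversed with barcodes seen with 1 element, none of them past the threshold there, were ATF4_3 on element 10 (-0.15), FOSL1_4 on element 100 (-0.33), GABPA_9 on element 64 (-0.24), control_25 on element 101 for concentration (-0.49), GABPA_7 guide-wide (0.013), and GABPA_9 (0.017) and control_24 (-0.022) in abundance. Guide-wide, with control gRNAs as the reference, they were FOSL1_6 (-0.074), GABPA_9 (-0.062), control_24 (-0.054), MYC_15 (-0.033), ATF4_2 (-0.028) and GATA1_12 (-0.022). GABPA_7 reversed guide-wide with library totals (0.018) and as the median of pair effects fitted with library totals (0.021). GATA1_10 reversed guide-wide with distinct barcodes (0.0063), and FOSL1_4 (0.0043) and GATA1_10 (0.10) at day 10. In abundance they were control_24 (-0.0021) and SP1_18 (-0.0007) with the control reference, and GABPA_7 with distinct barcodes (0.0046). Counting depth limits some constructs, such as MYC_13 on element 64, with a median of 2 counts in RNA, and ATF4_2 on element 49, with a median of 9.5 in DNA. The comparison of UMIs with reads was not run.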

Other observations

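No test was run in this part, and its values were chosen after they were seen. The gRNAs differed in how many of their associated barcodes were counted in cells: SP1_18 had 38.5%, while the other 25 gRNAs lay between 30.3% and 33.3%. Of DNA barcode and element combinations, 30.1% ± 1.12 (SD, n = 3) had RNA in the same-numbered library at day 5 lowMOI and 59.6% ± 3.69 at day 5 highMOI, against 25.2% ± 2.35 and 38.0% ± 2.51 at day 10. These shares rise with RNA depth, which differed. Mean RNA totals were 1665716 and 3894224 counts at day 5 and 1207558 and 2400083 at day 10 (lowMOI, then highMOI). The shares therefore do not measure how much of the DNA gives RNA. Of RNA combinations, 72.6% ± 3.74 and 74.1% ± 3.15 had DNA at day 5, and 38.8% ± 5.90 and 59.6% ± 4.23 at day 10.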
